A study of Homo sapiens with 24 samples.

How the data were processed

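Expression values were the TPM deposited by the authors for 57773 genes in 24 libraries; every column summed to 1e+06. Per the labels' protocols, SKOV3.ip1 cells were transfected with 100 nM siRNA or mock transfected, and RNA was taken 72 h later. Per the same protocols, ribodepleted total RNA was fragmented at 94 °C for 7 min, copied with a thermostable group II intron reverse transcriptase (TGIRT) and amplified for 12 PCR cycles. Per the submitters' processing notes, reads were handled with FastQC 0.10.1, Trimmomatic 0.38, TopHat2 2.0.9, Bowtie2 2.1.0.0 and SAMtools 0.1.19.0 against the hg19 assembly. The tool and annotation that produced the TPM table, the use of strand in counting and the sequencing depth are not stated in the labels or the processing notes. Overlapping and antisense genes, snoRNAs inside host genes and near-identical gene copies therefore have an uncertain assignment. Read data and splicing were not analysed here.

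Values were scaled with median-ratio factors over the 22727 genes above 0 in all libraries (factors 0.664 to 1.41), because structured RNAs took a share of the TPM that varied between libraries, and were analysed as log2 of the scaled value plus 1. This pseudocount makes the fold changes of weakly expressed genes too small. Genes with at least 1 TPM in at least 2 libraries were tested, 16994 in number. The model in limma 3.58.1 (R 4.3.3) had the 12 groups (8 siRNA groups, 4 mock sets, 2 libraries each) and empirical Bayes moderation with a mean-variance trend, with 12 residual and 3.04 prior degrees of freedom. For each protein the mean of both siRNAs, each minus its own mock set, was tested; a gene was called at a Benjamini-Hochberg adjusted p under 0.05 with the same sign for both siRNAs, and the difference between siRNAs was tested in the same model. Mock sets were matched to siRNAs by the siRNA label of each mock sample, which names the depletions it is the control for.

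A set of 26 gene lists, fixed before the values were seen, was tested with camera at a preset correlation of 0.01, adjusted over all lists and proteins; 22 had at least 5 tested members. Of the 17 calls, 0 hold with an estimated correlation. Overlaps with RBFOX2 were tested with Fisher's exact test, and the agreement of siRNAs was compared with 100 simulations without effects that kept the shared mock libraries. GC content and gene type came from GENCODE by gene identifier (16260 of the tested genes matched); its assembly is not the one of the deposited table, and no coordinates were used.

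Genes were named by a rule fixed beforehand: the 4 targeted genes; for each protein the 8 risen and 8 fallen called genes with the largest smaller-siRNA effect among those with a mean scaled value of at least 5 and a symbol not based on a clone. The rule added up to 3 called members by effect of each list past its threshold and of the interferon, LASR, epithelial and mesenchymal lists; up to 5 genes called in the same direction as after RBFOX2 depletion; and up to 3 per direction that differed between siRNAs. Other genes are marked in the text, and a few genes that the rule names are not reported.

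The alternatives tried were the values as deposited, quantile normalisation, a common total over genes other than small structured RNAs, a pseudocount of 0.1, no filter, a filter at 5 TPM, replicate number as a block, no trend and robust empirical Bayes. The others were all 8 mock libraries as control, fits on the groups of a single comparison, each siRNA alone, leaving out each library, a correction for GC content with and without the block, and leaving out the pair of libraries picked by eye.

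In a self-test, known changes were added to 200 of 16994 genes in simulated libraries of the same design. Genes and libraries were drawn independently with the fitted spreads, and both siRNAs of a protein had the same change. Deviations shared by libraries, GC trends and differences between siRNAs were not simulated. The shares and counts below therefore hold only where the model does. At a log2 change of 0.5 the share recovered was 49% for RBFOX2, 51% for hnRNPC, 78% for hnRNPM and 71% for SRSF1, and at a log2 change of 1 it was 89%, 84%, 93% and 98%. Unchanged genes called numbered 7, 10, 8 and 12; 0 calls had the wrong sign and 0 unchanged genes were called as differing between siRNAs.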

Results

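RNA abundance was measured by TGIRT-seq in 24 libraries of SKOV3.ip1, a derivative of the human ovarian carcinoma line SKOV-3. TGIRT-seq copies ribosomal-RNA-depleted, fragmented total RNA with a thermostable group II intron reverse transcriptase, which reads through structured RNAs as well as messenger RNAs. RBFOX2, hnRNPC, hnRNPM and SRSF1, which all bind RNA and regulate splicing, were each depleted with 2 siRNAs at 100 nM, and RNA was taken 72 h after transfection. The 8 siRNA groups and 4 mock sets (transfection reagent without siRNA) held 2 libraries each, which the series describes as biological replicates. The mock sets are named here as in the labels: n4/n5 for RBFOX2, oct for both hnRNPC siRNAs and hnRNPM siRNA_1, nov for SRSF1 siRNA_1, and jan for hnRNPM siRNA_3 and SRSF1 siRNA_3. The deposited values were TPM, a measure relative to each library's total, so the sequencing depth of each library is unknown. Small structured RNA genes took between 64.7% and 81.0% of the TPM in a library, and between 12637 and 15734 genes reached 1 TPM. Of the 276 pairs of libraries, 0 held identical values.

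Mock sets differed from one another, so each siRNA was compared with its own set. Between the oct and n4/n5 sets 188 genes differed by limma, 82 higher and 106 lower in oct, against 3 between oct and jan and 45 between nov and jan. Between oct and nov limma called 0 genes, with 2295 at an unadjusted p under 0.05. Several replicates differed on the principal components: mock nov (-14.1 and 18.9 on the first), hnRNPM siRNA_3 (-6.11 and 18.6 on the third), mock oct (11.6 and -9.70 on the third) and hnRNPC siRNA_2 (-11.8 and -33.1 on the fourth). Mock nov replicate 1 and hnRNPC siRNA_2 replicate 3 were picked by eye, after the components were seen, as a pair to leave out in one alternative.

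Each targeted gene fell in the libraries of its own siRNAs. RBFOX2 stood at 17.0 ± 1.03 scaled TPM (SD, n = 2) in its mock set, 5.43 ± 0.0304 with siRNA_1 and 4.37 ± 0.308 with siRNA_2. HNRNPC stood at 147 ± 26.9 in the oct mock set, 44.3 ± 1.65 with siRNA_2 and 39.9 ± 3.42 with siRNA_3. HNRNPM stood at 8.80 ± 0.839 with siRNA_1 against 37.8 ± 6.81 in its mock set, and at 11.9 ± 0.900 with siRNA_3 against 40.4 ± 1.69. SRSF1 stood at 51.8 ± 0.0542 with siRNA_1 against 227 ± 0.421 in its mock set, and at 42.4 ± 3.49 with siRNA_3 against 199.6 ± 16.9. Over both siRNAs the log2 fold changes were -1.61 for RBFOX2 (SE 0.0712, limma adjusted p = 8.54e-09), -1.77 for HNRNPC (SE 0.104, adjusted p = 1.85e-07), -1.83 for HNRNPM (SE 0.0989, adjusted p = 7.93e-08) and -2.16 for SRSF1 (SE 0.146, adjusted p = 6.22e-07). On the fitted scale, with 1 added to each value, these correspond to 32.7%, 29.3%, 28.1% and 22.4% of mock. The added 1 makes the remaining level look too high, most of all for RBFOX2, the most weakly expressed of the 4. None of the 4 genes passed the test in another protein's comparison (adjusted p from 0.150 for HNRNPM after SRSF1 depletion to 0.980 for HNRNPM after RBFOX2 depletion).

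**Figure D1:**
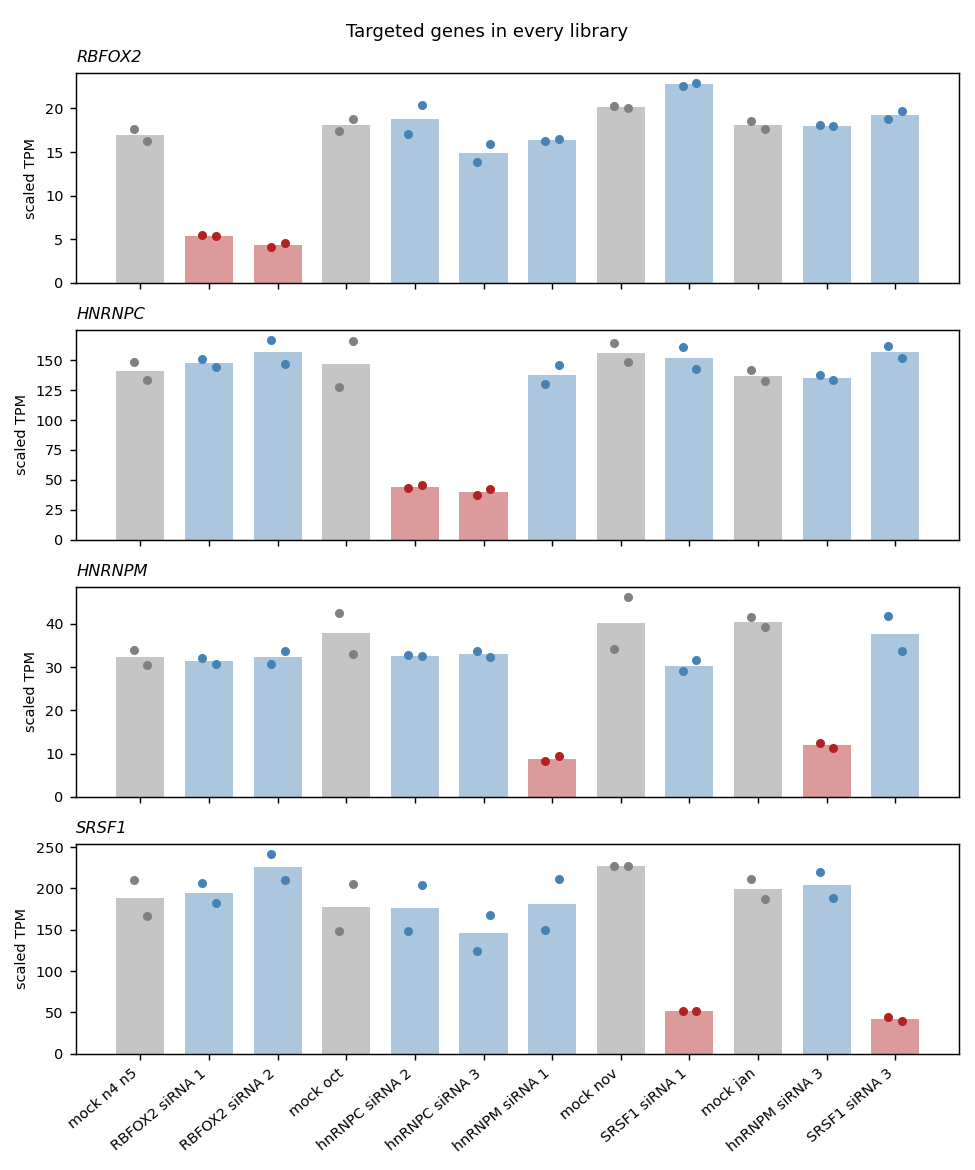
Scaled TPM (vertical axis, linear from 0) of RBFOX2, HNRNPC, HNRNPM and SRSF1 in the 12 groups of libraries; bars are means and points are the 2 libraries of each group. Each gene is lowest in the siRNA groups directed against it, for example 5.43 and 4.37 for RBFOX2 against 17.0 in its mock set.

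RBFOX2, a splicing regulator that binds GCAUG elements, was the protein the series centres on. By limma 4 genes rose and 15 fell out of 16994 tested (2081 at an unadjusted p under 0.05), among them RBFOX2 itself. AKR1C2, an aldo-keto reductase that metabolises steroids, fell from 26.9 ± 3.85 scaled TPM (n = 2) to 12.5 ± 3.01 (n = 4), a log2 change of -1.06 (SE 0.139, adjusted p = 0.0112); its reads are shared in part with the near-identical AKR1C1. THBD, which encodes the anticoagulant receptor thrombomodulin, fell by 0.61 on the log2 scale (SE 0.0827, adjusted p = 0.0112), by 1.16 with siRNA_1 and by 0.06 with siRNA_2. CYBRD1, a duodenal-type ferric reductase, changed by -0.67 (SE 0.113, adjusted p = 0.0345), TRIM16L by -0.58 (SE 0.0873, adjusted p = 0.0189) and the collagen gene COL12A1 by -0.42 (SE 0.0673, adjusted p = 0.0250). C7orf50 rose by 0.36 (SE 0.0519, adjusted p = 0.0166), PPP1R18 by 0.36 (SE 0.0641, adjusted p = 0.0447) and the cell cycle transcription factor E2F4 by 0.35 (SE 0.0572, adjusted p = 0.0299). ASPH, FAM20B, ANKRD36B and TMEM245 also fell, by 0.41, 0.36, 0.36 and 0.41; TRIM16L and ANKRD36B have close copies elsewhere in the genome.

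Apart from RBFOX2 itself these calls depended on single libraries. The count was 1 without mock replicate 4, 3 without mock replicate 5, 1 without siRNA_1 replicate 4, 4 without siRNA_1 replicate 5 and 1 without siRNA_2 replicate 4, and it stayed close, at 17, only without siRNA_2 replicate 5. Each of the 12 named calls was lost without at least 1 library: AKR1C2 without mock replicate 4 (adjusted p = 0.0685), mock replicate 5 (0.111), siRNA_1 replicate 4 (0.0558) and siRNA_2 replicate 4 (0.0557), and THBD without the same 4 (0.109, 0.115, 0.0558 and 0.0592). With the values as deposited the median of all genes moved by 0.21 on the log2 scale and 3 genes rose and 1 fell, so that 75% of calls were upward against 21.1% after scaling. With replicate number as a block 184 genes rose and 179 fell, 50.7% upward, and the 12 named calls were kept. What that number marks is not stated in the labels. RBFOX2 was the 1 gene called when only the RBFOX2 libraries and their mock set entered the fit; AKR1C2 then stood at an adjusted p of 0.220.

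Among the gene lists, genes of the G1/S transition were higher after RBFOX2 depletion. Of 22 tested members 21 were higher than in mock, with a median log2 fold change of 0.22 (0.21 with siRNA_1 and 0.25 with siRNA_2) and a camera adjusted p of 1.69e-07 (adjusted p = 0.799 with an estimated correlation). No member passed the test over all genes, and 6 rose adjusted over the list alone. The DNA replication genes GINS2 (0.55, adjusted p = 0.0686), CDC45 (0.61, adjusted p = 0.206), MCM7 (0.42, adjusted p = 0.201) and MCM5 (0.38, adjusted p = 0.140) are given as examples chosen after their values were seen. Core spliceosome genes were higher in 26 of 30, with a median of 0.10 and an adjusted p of 0.00209 (adjusted p = 0.799 with an estimated correlation); 0 members passed over all genes and 1 rose adjusted over the list alone. Both lists kept their call without each library in turn, with an adjusted p of at most 0.00873 and 0.0210, but the G1/S median was 0.12 without mock replicate 5 and 0.31 without mock replicate 4.

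A further 5 lists passed the camera threshold after RBFOX2 depletion, with 0 members called over all genes in any of them. The replication-dependent histones were higher in 21 of 21 members (median 0.22, adjusted p = 0.0481, 0 adjusted over the list alone; adjusted p = 0.853 with an estimated correlation). The hnRNP family was higher in 22 of 28 (median 0.08, camera adjusted p = 0.0333, and 0.853 with an estimated correlation), with 1 rising adjusted over the list alone. Its median ran from 0.002 to 0.209 when single libraries were left out. Factors of nonsense-mediated decay were higher in 12 of 15 (median 0.08, adjusted p = 0.0280, 3 rose adjusted over the list alone; adjusted p = 0.799 with an estimated correlation). Hypoxia and glycolysis genes were lower in all but 3 of 19 (median -0.13, but -0.23 with siRNA_1 and -0.03 with siRNA_2, adjusted p = 0.00209, 3 fell adjusted over the list alone; adjusted p = 0.799 with an estimated correlation), although with the values as deposited, which moved the median of all genes by 0.21, their median was 0.10 and the call was kept (0.0337). BNIP3 stood at -0.38 (adjusted p = 0.192) and LDHA at -0.28 (adjusted p = 0.196), both chosen after their values were seen. Host genes of snoRNAs were lower in all but 2 of 14 (median -0.22, adjusted p = 0.0333, 0 adjusted over the list alone; adjusted p = 0.799 with an estimated correlation), although with the values as deposited their median was 0.05, again with the call kept (0.0301). GAS5, chosen in the same way, stood at -0.49 (adjusted p = 0.581).

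Across 11270 protein-coding genes the RBFOX2 fold changes followed GC content (rank correlation 0.425), and the mock libraries of this set differed in the same respect, at -0.190 for replicate 4 and 0.529 for replicate 5. Without mock replicate 5 the adjusted p was 0.961 for the hnRNP family, 0.124 for the decay factors, 0.141 for the snoRNA hosts, 0.0561 for the hypoxia genes and 0.563 for the histones, whose median turned to -0.10. The hnRNP family also lost its call without siRNA_1 replicate 4 (0.102) and siRNA_2 replicate 4 (0.174), the histones without the same libraries (0.395 and 0.391), and the snoRNA hosts without siRNA_1 replicate 5 (0.0573) and siRNA_2 replicate 5 (0.0518). After a correction for GC content the snoRNA hosts (adjusted p = 0.0596) and the histones (0.0562) no longer passed. Of the 19 genes 10 were still called after it, and C7orf50 (0.21, adjusted p = 0.130), PPP1R18 (0.27, 0.161), E2F4 (0.24, 0.104), ANKRD36B (-0.32, 0.104), ASPH (-0.36, 0.0906) and TMEM245 (-0.38, 0.0524) were not. A filter at 5 TPM ended the calls of the hnRNP family (0.0638), the snoRNA hosts (0.0521) and the histones (0.0757), and quantile normalisation those of the decay factors (0.0602) and the snoRNA hosts (0.488).

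hnRNPC, a nuclear protein that binds uridine tracts in nascent transcripts, gave 359 genes that rose and 737 that fell after depletion (limma, 3551 at an unadjusted p under 0.05). The largest increases were in gene copies of small RNAs. RN7SKP71, a copy of the 7SK RNA gene, rose from 49.3 ± 11.7 scaled TPM (n = 2) to 725 ± 174 (n = 4), 14.3-fold on the fitted scale (log2 change 3.84, SE 0.217, adjusted p = 1.53e-07). The U6 copy RNU6-36P rose by 3.70 (SE 0.322, adjusted p = 2.18e-05), RNU6-15P by 3.50, RNU6-11P by 3.33 and RNU6-5P by 2.83. RN7SL5P, a copy of the signal recognition particle RNA, rose from 584 ± 160 to 4649 ± 328 scaled TPM (log2 change 3.02, SE 0.310, adjusted p = 5.91e-05). In the other direction the 7SK copy RN7SKP80 changed by -2.32 (SE 0.250, adjusted p = 8.97e-05), a gene carrying the shared symbol Y_RNA by -1.64 (SE 0.292, adjusted p = 0.00395). HNRNPCP2, a processed copy of HNRNPC, changed by -2.24 (SE 0.127, adjusted p = 1.53e-07). Copies of one family share reads, and how the counting divided them is not stated in the labels or the processing notes, so the assignment to a single copy is uncertain. Among protein-coding genes SOD2, the mitochondrial superoxide dismutase, fell from 73.4 ± 3.63 to 40.8 ± 4.20 scaled TPM (log2 change -0.84, SE 0.134, adjusted p = 0.00187).

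The calls of RN7SKP71, RNU6-36P, RNU6-15P, RNU6-11P, RNU6-5P, RN7SL5P, RN7SKP80, HNRNPCP2 and SOD2 held without each library in turn, while that of Y_RNA was lost without mock oct replicate 3 (adjusted p = 0.0564). SOD2 did not pass against all 8 mock libraries (-0.36, adjusted p = 0.393) or with the hnRNPC libraries and their mock set fitted alone (adjusted p = 0.0703). The count of 1096 genes was 670 without siRNA_2 replicate 3, 710 without siRNA_3 replicate 1, 657 without mock oct replicate 1 and 369 without mock oct replicate 3, and 706 without the pair of libraries picked by eye. With the values as deposited 287 genes were called, 22.3% of them upward against 32.8% after scaling, and the median of all genes moved by -0.14; with only the hnRNPC libraries and their mock set 58 were called, 81.0% upward.

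Targets of NF-kB and inflammatory genes were lower after hnRNPC depletion in all but 1 of 17 tested members, with a median of -0.28 (-0.25 with siRNA_2 and -0.30 with siRNA_3) and a camera adjusted p of 0.000825 (adjusted p = 0.799 with an estimated correlation). This call held without each library in turn. Over all genes 4 fell, and 6 fell adjusted over the list alone. BIRC3, an inhibitor of apoptosis, changed by -0.74 (SE 0.131, adjusted p = 0.00395), the cytokine gene IL1A by -0.72 (SE 0.199, adjusted p = 0.0430) and TNFAIP3, which encodes the feedback inhibitor A20, by -0.43 (SE 0.104, adjusted p = 0.0217). BIRC3 lost its call without mock oct replicate 3 (adjusted p = 0.0724), IL1A without any library but mock oct replicate 1 (up to 0.430) and TNFAIP3 without any but the replicates 1 of both siRNAs (up to 0.157). Against all 8 mock libraries none of the 3 passed, BIRC3 standing at -0.20 (adjusted p = 0.612), IL1A at an adjusted p of 0.165 and TNFAIP3 at 0.135.

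Genes of cholesterol synthesis were higher in 17 of 23 members after hnRNPC depletion (median 0.13, camera adjusted p = 0.00457; adjusted p = 0.799 with an estimated correlation), although with the values as deposited the median was -0.02 and the list did not pass. The median was -0.06 with siRNA_2 and 0.40 with siRNA_3. HSD17B7 (0.57, SE 0.109, adjusted p = 0.00622) and the regulator SREBF2 (0.33, SE 0.0858, adjusted p = 0.0309) rose, 2 over all genes and 4 adjusted over the list alone. Hypoxia and glycolysis genes were lower in all but 4 of 19 (median -0.16, but -0.02 with siRNA_2 and -0.18 with siRNA_3, adjusted p = 0.0333; adjusted p = 0.799 with an estimated correlation). Over all genes 3 fell, and 3 adjusted over the list alone, BNIP3 by 0.51, HK2 by 0.45 and P4HA1 by 0.40. Histones were higher in 19 of 21 (median 0.19, adjusted p = 0.0333; adjusted p = 0.853 with an estimated correlation), with HIST2H2BE (0.58, adjusted p = 0.0457) called over all genes and 0 adjusted over the list alone. The list of RBFOX partners in the large assembly of splicing regulators (LASR) was lower (median -0.19, adjusted p = 0.0333; adjusted p = 0.799 with an estimated correlation). Its 1 called member, also 1 adjusted over the list alone, was HNRNPC itself, and the other 7 gave an unadjusted p of 0.140.

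Library dependence was marked in these 4 lists. The median of the cholesterol list ran from 0.04 to 0.21 when single libraries were left out. The cholesterol list lost its call without siRNA_2 replicate 1 (adjusted p = 0.0821), siRNA_3 replicate 1 (0.0590) and mock oct replicate 3 (0.314). The hypoxia list lost its call without siRNA_3 replicate 3 (0.0813) and mock oct replicate 1 (0.153), and the LASR list without siRNA_2 replicate 1 (0.116), siRNA_3 replicate 1 (0.0659) and mock oct replicate 1 (0.0596). The histones lost it without siRNA_2 replicate 3 (0.257), siRNA_3 replicate 3 (0.124) and mock oct replicate 1 (0.971, with a median of -0.09), as well as without the pair of libraries picked by eye (0.250). The mock oct replicates had rank correlations with GC content of 0.384 and -0.429. A filter at 5 TPM ended the calls of the hypoxia (0.273) and LASR (0.0795) lists, and the histones lost theirs with quantile normalisation (0.125), without a filter (0.0524) and after the GC correction (0.0863). Among the named members, HSD17B7 lost its call without mock oct replicate 3 (0.0611) and with the values as deposited (0.213), BNIP3 without siRNA_2 replicate 3 (0.0517) and mock oct replicate 3 (0.171). SREBF2, HK2, P4HA1 and HIST2H2BE each lost theirs without at least 4 of the 6 libraries.

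**Figure D2:**
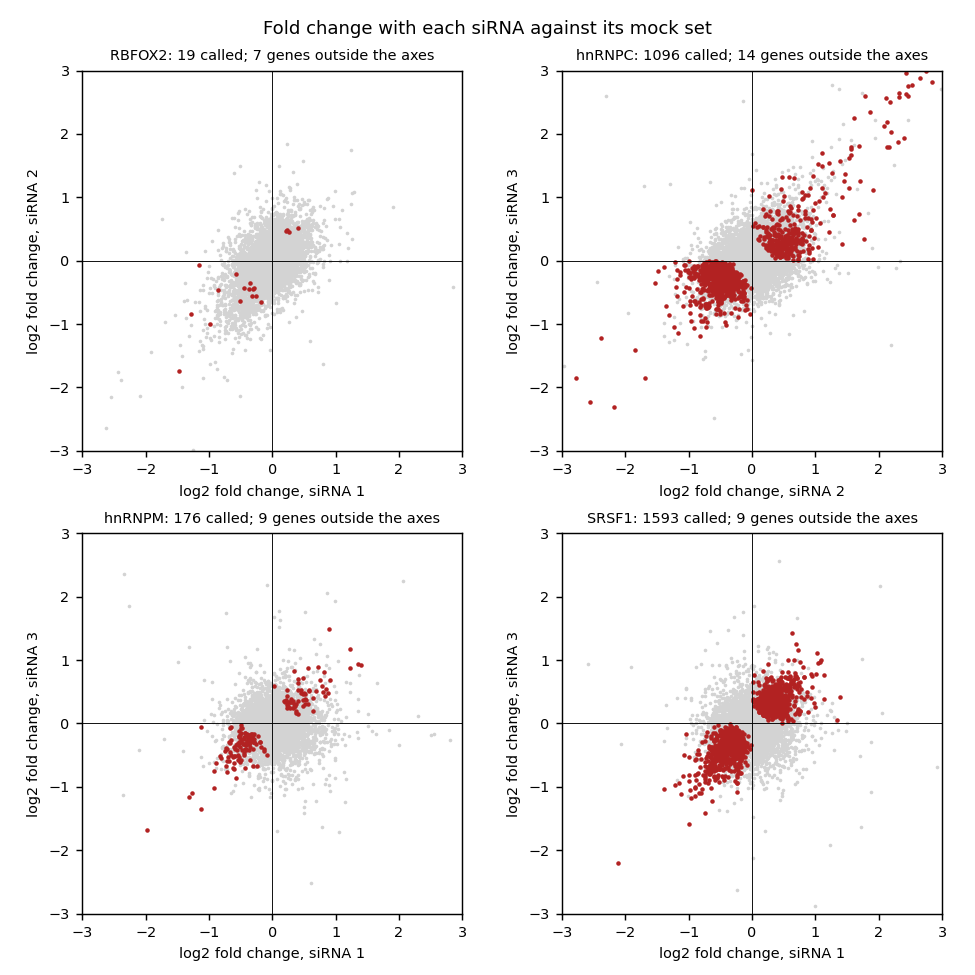
Log2 fold change against mock with one siRNA (horizontal axis) and the other (vertical axis) for every tested gene, 1 panel per protein; genes called over both siRNAs are red, and a few genes lie outside the axes. The correlation across genes was 0.556 for RBFOX2 and 0.539 for hnRNPC, whose siRNAs share mock libraries, and 0.0905 for hnRNPM and 0.340 for SRSF1, whose siRNAs do not.

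hnRNPM, a splicing regulator that binds GU-rich RNA, gave 61 genes that rose and 115 that fell after depletion (limma, 1834 at an unadjusted p under 0.05). EIF4G3, a scaffold of cap-dependent translation initiation, fell from 15.5 ± 2.11 scaled TPM (n = 4) to 6.35 ± 1.40 (n = 4), a log2 change of -1.18 (SE 0.0744, adjusted p = 3.51e-07). The heat shock transcription factor HSF2 changed by -1.23 (SE 0.0801, adjusted p = 4.41e-07), ESYT2, which tethers the endoplasmic reticulum to the plasma membrane, by -0.84 (SE 0.0481, adjusted p = 1.33e-07), PCMTD2 by -0.74 and TMCO3 by -0.70. The zinc finger gene ZNF548 rose from 4.46 ± 0.184 to 11.3 ± 2.22 scaled TPM, 2.23-fold on the fitted scale (log2 change 1.16, SE 0.0567, adjusted p = 3.75e-08). MED15, a subunit of the Mediator complex, rose by 0.60 (SE 0.0755, adjusted p = 0.000562), and NDUFV2, of respiratory complex I, and HEXA, the lysosomal hexosaminidase, by 0.49 and 0.48. IGKV1OR-2 (1.19) and TMEM14D (0.82) with TMEM14B (0.64) also rose, all of them with near-identical copies that leave the assignment uncertain.

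Of the 18 named hnRNPM calls, 17 held without each library in turn; that of the interferon-induced nuclease ISG20 (0.47, SE 0.0948, adjusted p = 0.0261) was lost without every library but hnRNPM siRNA_3 replicate 1 (up to 0.143). The count of 176 genes was 80 without mock jan replicate 1, 87 without mock jan replicate 2, 112 without siRNA_1 replicate 1, 80 without siRNA_1 replicate 3 and 84 without siRNA_3 replicate 2. With the values as deposited 42 genes were called, MED15 (adjusted p = 0.264), NDUFV2 (0.376) and HEXA (0.410) not among them. When only the hnRNPM libraries and their mock sets entered the fit 37 were called, MED15 (0.0607), HEXA (0.107), TMEM14D (0.107) and TMEM14B (0.107) not among them. The hnRNPM fold changes followed GC content (rank correlation 0.412 across protein-coding genes).

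Genes of the ATF4 and endoplasmic reticulum stress response were lower after hnRNPM depletion in all but 3 of 22 members, with a median of -0.12 and a camera adjusted p of 5.70e-05 (adjusted p = 0.710 with an estimated correlation). Leaving out each library in turn did not end this call. Over all genes 1 fell; adjusted over the list alone 8 fell and 1 rose. The called member was PSAT1, an enzyme of serine synthesis (-0.59, SE 0.0738, adjusted p = 0.000526), which stood at -1.13 with siRNA_1 and -0.05 with siRNA_3 and did not pass with only the hnRNPM libraries and their mock sets (adjusted p = 0.107). Others, chosen after their values were seen, were PHGDH of the same pathway at -0.35 (adjusted p = 0.0830), the chaperone gene HSPA5 at -0.43 (adjusted p = 0.264) and DNAJB9 at -0.25 (adjusted p = 0.0642). The LASR list was lower in 8 of 8 members over both siRNAs (median -0.05, but -0.11 with siRNA_1 and 0.00 with siRNA_3, adjusted p = 0.0333; adjusted p = 0.799 with an estimated correlation). Its 1 called member, also 1 adjusted over the list alone, was HNRNPM itself, and the other 7 gave an unadjusted p of 0.337. That call was lost without mock jan replicate 1 (0.115), mock oct replicate 3 (0.0818), siRNA_1 replicate 1 (0.169) and siRNA_3 replicate 2 (0.109). It was also lost after the GC correction (0.0855), with a filter at 5 TPM (0.0638) and with only the hnRNPM libraries and their mock sets (0.0654).

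SRSF1, a serine/arginine-rich splicing factor, gave 741 genes that rose and 852 that fell after depletion (limma, 3952 at an unadjusted p under 0.05), of which 4 rose and 11 fell at least 2-fold. MAPK8IP3, a scaffold of JNK signalling, rose from 5.80 ± 0.421 scaled TPM (n = 4) to 12.8 ± 0.651 (n = 4), 2.03-fold on the fitted scale (log2 change 1.02, SE 0.0965, adjusted p = 1.56e-05). HLA-DMB, a chaperone of MHC class II peptide loading, rose by 0.95 (SE 0.132, adjusted p = 0.000372), PGAP3 by 0.94, the secreted glycoprotein gene MFGE8 by 0.90 (SE 0.0837, adjusted p = 1.52e-05). Others that rose were SPARC by 0.85 (SE 0.167, adjusted p = 0.00468), LENG8 by 0.77 and CHPF2 by 0.70. FTSJ3, which acts in ribosomal RNA maturation, fell from 13.1 ± 0.693 to 5.52 ± 0.291 scaled TPM (log2 change -1.12, SE 0.0645, adjusted p = 1.05e-07). RFC1, the large subunit of the clamp loader of DNA replication, fell from 19.9 ± 1.70 to 9.36 ± 0.842 (log2 change -1.01, SE 0.0579, adjusted p = 1.05e-07). S100P changed by -1.21 (SE 0.158, adjusted p = 0.000261), CTH, which makes cysteine from cystathionine, by -1.09 (SE 0.0913, adjusted p = 4.89e-06), LCN2 by -1.07 (SE 0.221, adjusted p = 0.00648) and PECR by -0.96.

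All of these calls held without each library in turn. That of RNU1-3, a U1 RNA copy at -5.84 (SE 1.63, adjusted p = 0.0349), was lost without 6 of the 8 libraries, and its scaled TPM ran from 0.191 to 5816 among the 4 depleted libraries. Against all 8 mock libraries HLA-DMB (0.58, adjusted p = 0.284) and SPARC (0.43, adjusted p = 0.431) did not pass, and with the values as deposited LENG8 (0.0820) and CHPF2 (0.0658) did not. The count of 1593 genes was 957 without mock jan replicate 1, 972 without mock jan replicate 2 and 919 without siRNA_1 replicate 2. From the values as deposited 249 genes were called, 35.3% of them upward against 46.5% after scaling, and with a common total over the other genes 868 rose and 677 fell, so which direction was the more frequent depended on the scaling.

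NF-kB targets were higher after SRSF1 depletion in 13 of 17 members, with a median of 0.31 (0.34 with siRNA_1 and 0.16 with siRNA_3) and a camera adjusted p of 0.00303 (adjusted p = 0.799 with an estimated correlation). Over all genes 7 rose, and 9 rose and 1 fell adjusted over the list alone. BIRC3 rose by 0.77 (SE 0.107, adjusted p = 0.000372), TNF by 0.42 (SE 0.118, adjusted p = 0.0365) and NFKB1 by 0.36 (SE 0.0960, adjusted p = 0.0268). The list kept its call without each library in turn but not with a filter at 5 TPM (adjusted p = 0.0638). The call of TNF was lost without all libraries but mock jan replicate 2 and mock nov replicate 1 (up to 0.165) and that of NFKB1 without all but mock nov replicate 2 (up to 0.115).

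Cholesterol synthesis genes were higher after SRSF1 depletion in 18 of 23 members (median 0.12, camera adjusted p = 0.0107; adjusted p = 0.799 with an estimated correlation). Over all genes 3 rose, and 7 adjusted over the list alone, among them MSMO1 by 0.24 (SE 0.0639, adjusted p = 0.0259) and SC5D by 0.24 (SE 0.0657, adjusted p = 0.0321). Cytosolic ribosomal protein genes were lower in all but 3 of 46 (median -0.15, adjusted p = 7.37e-05; adjusted p = 0.799 with an estimated correlation), -0.21 with siRNA_1 and -0.07 with siRNA_3. Of these 3 fell over all genes and 3 adjusted over the list alone, RPS18 by 0.35 (SE 0.0941, adjusted p = 0.0269), RPS12 by 0.30 (SE 0.0685, adjusted p = 0.0122) and RPS6 by 0.25 (SE 0.0704, adjusted p = 0.0332). All have processed pseudogenes that share their reads. Both lists kept their calls without each library in turn, the ribosomal list not with quantile normalisation (adjusted p = 0.0676). The ribosomal median was -0.09 without mock nov replicate 1 and -0.20 without mock nov replicate 2. As deposited, the values left MSMO1 (0.376), SC5D (0.347), RPS18 (0.197), RPS12 (0.352) and RPS6 (0.408) uncalled. RPS12 lost its call without siRNA_3 replicate 1 (0.0519) and mock jan replicate 2 (0.0577), and MSMO1, SC5D, RPS18 and RPS6 each without at least 4 of the 8 libraries (up to 0.133 for RPS18).

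The interferon-stimulated list did not pass for any protein, but single members changed after SRSF1 depletion: 6 rose and 1 fell of 29 tested, 7 and 1 adjusted over the list alone (camera adjusted p = 0.0862). BST2, which tethers budding virions, rose by 0.63 (SE 0.114, adjusted p = 0.00286), without loss of the call when each library was left out. Against all 8 mock libraries BST2 stood at 0.35 (adjusted p = 0.145). IFI27 stood at -0.65 (SE 0.164, adjusted p = 0.0209; lost without 5 of the 8 libraries, up to 0.108). After hnRNPC depletion 2 members fell, also 2 adjusted over the list alone (adjusted p = 0.572), among them HERC6 by 0.42 (adjusted p = 0.00646), which lost its call without mock oct replicate 3 (0.0956). After hnRNPM depletion ISG20 was the 1 member called, also 1 adjusted over the list alone (adjusted p = 0.572), and after RBFOX2 depletion 0 were called by limma and 1 fell adjusted over the list alone (adjusted p = 0.682).

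Epithelial and mesenchymal markers changed in both directions. After SRSF1 depletion the keratin gene KRT7 fell by 0.69 (SE 0.109, adjusted p = 0.00112) and the splicing regulator ESRP1 by 0.37 (SE 0.0920, adjusted p = 0.0184), while the protease inhibitor gene SPINT2 rose by 0.33 (SE 0.0747, adjusted p = 0.0108). Of 19 epithelial members 1 rose and 3 fell, 2 and 5 adjusted over the list alone (camera adjusted p = 0.285). Of 19 mesenchymal members 3 rose and 1 fell, 3 and 2 adjusted over the list alone (adjusted p = 0.381), with SPARC at 0.85, TGFBI at 0.62 (SE 0.164, adjusted p = 0.0254) and the receptor tyrosine kinase gene AXL at -0.71 (SE 0.169, adjusted p = 0.0149). After hnRNPC depletion KRT7 fell by 0.60 (SE 0.134, adjusted p = 0.0155) and KRT19 by 0.42 (SE 0.106, adjusted p = 0.0280), the 2 epithelial members called over all genes against 3 adjusted over the list alone (adjusted p = 0.115, and 0.0334 with the values as deposited). KRT19 stood at -0.09 with hnRNPC siRNA_2 and -0.76 with siRNA_3 (limma adjusted p of the difference 0.00304). CYR61 (0.61, adjusted p = 0.0271) and LOX (0.40, adjusted p = 0.0192) were the 2 mesenchymal members that rose there, with 2 rising and 1 falling adjusted over the list alone (adjusted p = 0.652). KRT7 and SPINT2 after SRSF1 depletion held without each library in turn. ESRP1, AXL, KRT19, CYR61 and TGFBI each lost their call without at least 4 libraries (up to 0.210 for KRT19). KRT7 after hnRNPC depletion lost its call without siRNA_3 replicate 1 (0.0509) and mock oct replicate 3 (0.223), and LOX without 3 libraries (up to 0.106). Against all 8 mock libraries the calls of SPINT2 (0.0872), TGFBI (0.101) and CYR61 (0.153) ended.

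Among splicing factors SRSF1 depletion lowered HNRNPH1, a LASR member, by 0.51 (SE 0.0907, adjusted p = 0.00229), the 1 member of that list called over all genes and 1 adjusted over the list alone (camera adjusted p = 0.184). Its call held without each library in turn, and its adjusted p was 0.0755 with the values as deposited. TRA2A of the SR protein list was at -0.61 and HNRNPH3 of the hnRNP family at -0.68 after SRSF1 depletion, both called and chosen after their values were seen. In all, 2 members of each list fell over all genes and 2 adjusted over the list alone, SRSF1 and HNRNPH1 being the others (adjusted p = 0.184 and 0.131). After hnRNPC depletion SF3A3, a subunit of the U2 particle, was at -0.55 (adjusted p = 4.04e-05), with 1 spliceosome gene rising and 2 falling both over all genes and adjusted over the list alone (adjusted p = 0.397). Integrin and adhesion genes (4 rose and 1 fell after SRSF1 depletion, 5 and 1 adjusted over the list alone), p53 targets (1 rose and 3 fell, 1 and 3 adjusted over the list alone) and ATF4 and endoplasmic reticulum stress genes (1 rose and 4 fell, 2 and 8 adjusted over the list alone) did not pass camera (adjusted p = 0.222, 0.572 and 0.0584). After hnRNPC depletion p53 targets gave 3 that rose over all genes and 3 adjusted over the list alone (adjusted p = 0.115).

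In all, 17 of 88 tests of lists (22 lists for each of 4 proteins) passed the camera threshold with a preset correlation of 0.01, and 0 passed with an estimated correlation. The median, mean and test differed in sign for 10 of them, none past the threshold. They were tissue splicing regulators, integrins and ovarian carcinoma markers after RBFOX2 depletion, decay factors, snoRNA hosts and ribosomal proteins after hnRNPC depletion, p53 targets and G1/S genes after hnRNPM depletion, and hypoxia and RNA interference genes after SRSF1 depletion. The other 4 lists had under 5 tested members. All 37 mitochondrially encoded genes were listed at 0 in every library. Of the markers of other cell types 1 of 12 fibroblast and mesothelial genes was tested (UPK3B, mean 2.17 TPM as deposited), 1 of 10 endothelial genes (EGFL7, 8.18) and 0 of 14 leukocyte genes.

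**Figure D3:**
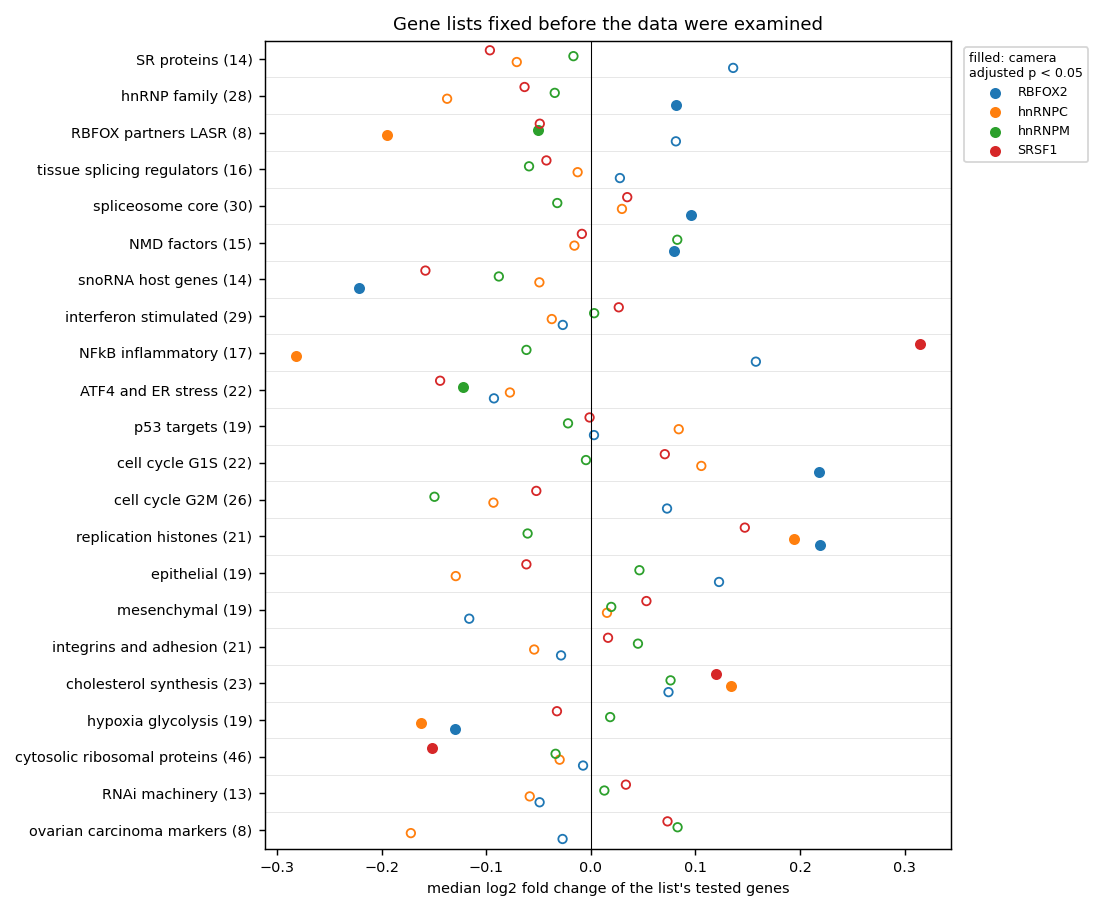
Median log2 fold change (horizontal axis) of each tested gene list after depletion of each protein; filled points mark a camera adjusted p under 0.05 at the preset correlation of 0.01. G1/S genes after RBFOX2 depletion (0.22) and NF-kB targets after hnRNPC (-0.28) and SRSF1 (0.31) depletion are among the filled points; with the values as deposited the medians of the hypoxia (0.10) and snoRNA host (0.05) lists after RBFOX2 depletion and of the cholesterol list (-0.02) after hnRNPC depletion change sign. Those values moved the median of all genes by 0.21 and -0.14 for these proteins, and of the 3 lists only the cholesterol list lost its call.

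Both siRNAs of a protein were compared with each other in the same model. For hnRNPC 1880 genes differed (limma, 4232 at an unadjusted p under 0.05), for RBFOX2 257 (2300), for hnRNPM 7 (882) and for SRSF1 1 (844). The mock libraries cancel in this comparison for hnRNPC and RBFOX2 but not for hnRNPM and SRSF1, whose standard errors are larger, so the counts are not comparable between proteins. With only the groups of each comparison 6 genes differed for hnRNPC and 0 for RBFOX2, and as deposited the values gave 541 and 22. ATL3, which shapes the endoplasmic reticulum, was at 0.20 with hnRNPC siRNA_2 and -1.02 with siRNA_3 (adjusted p of the difference 1.64e-05), and PINK1, a kinase of mitochondrial quality control, at -1.48 and -0.16 (1.64e-05). RBFOX2, the only targeted gene that differed between a pair of siRNAs, was 0.31 higher with hnRNPC siRNA_2 than with siRNA_3 (adjusted p = 0.0242). Of the 1096 hnRNPC calls, 331 also differed between the siRNAs. IGFBP6, which binds insulin-like growth factors, was at -1.06 with RBFOX2 siRNA_1 and 0.16 with siRNA_2 (adjusted p = 0.000168), and THBD was also among those that differed (0.000132). YWHAH was at -0.96 with hnRNPM siRNA_1 and 0.14 with siRNA_3 (adjusted p = 0.00996). The 1 gene for SRSF1, AC006262.5, was chosen after its values were seen (1.71 with siRNA_1 and -0.51 with siRNA_3, adjusted p = 0.0216).

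Counts of differences also moved with single libraries. For hnRNPC 518 genes differed without siRNA_2 replicate 3, 1171 without siRNA_3 replicate 1 and 864 without siRNA_3 replicate 3. For RBFOX2 29 and 32 differed without siRNA_1 replicates 4 and 5, and 41 and 72 without siRNA_2 replicates 4 and 5. For hnRNPM 1 and 0 differed without mock jan replicates 1 and 2, 4 and 2 without siRNA_1 replicates 1 and 3, and 1 and 4 without siRNA_3 replicates 1 and 2. For SRSF1 2 differed without mock nov replicate 1, and 0 without either mock jan library, mock nov replicate 2, either siRNA_1 library or siRNA_3 replicate 2. The fold changes of both siRNAs correlated across genes, which are not independent replicates, at 0.556 for RBFOX2 and 0.539 for hnRNPC, where unchanged groups simulated against the same mock libraries gave 0.497 and 0.497; the covariances were 0.0357 and 0.0565 against 0.0222 and 0.0221 simulated. Each mock set has 2 libraries, too few to leave 2 in each part of a split, and was not split, so the part of the excess that comes from the shared mock libraries is unknown. For hnRNPM and SRSF1, with separate mock sets, the correlations were 0.0905 and 0.340 against 0.000143 and -0.00441 simulated. After the correction for GC content, chosen after the data were seen, the correlations were 0.531, 0.531, 0.0769 and 0.341 in the order RBFOX2, hnRNPC, hnRNPM, SRSF1.

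The overlap of RBFOX2 with the other proteins bears on the series' question of how RBFOX2 works with partner proteins. The RBFOX2 libraries share no mock set with the others. All proteins share 1 estimate of spread per gene in the fit, so a gene with a small estimate is more easily called in both lists. The expected counts and the exact tests assume independent lists and do not account for this, so an excess does not by itself show shared regulation. With hnRNPC 4 genes were called in the same direction and 0 in opposite directions by limma, where independent lists would give 0.735 and 0.490 (Fisher's exact test for calls in both, adjusted p = 0.0459). They were ASPH (-0.41 after RBFOX2 and -0.44 after hnRNPC depletion), COL12A1 (-0.42 and -0.45), EDIL3 (-0.44 and -0.42) and E2F4 (0.35 and 0.21). Between the hnRNPC siRNAs ASPH (-0.11 with siRNA_2 and -0.77 with siRNA_3, adjusted p = 0.000235), COL12A1 (-0.66 and -0.24, 0.00325) and E2F4 (0.36 and 0.05, 0.00725) differed, as COL12A1 did between the RBFOX2 siRNAs (-0.18 and -0.65, 0.00612). With hnRNPM only THBD was shared (-0.61 and -0.46; 0.116 expected, exact adjusted p = 0.180). With SRSF1 4 genes moved the same way, AKR1C2 (-1.06 and -0.72), THBD (-0.61 and -0.74), TRIM16L (-0.58 and -0.33) and C7orf50 (0.36 and 0.20), and 3 the opposite way, where 0.926 and 0.855 would be expected (exact adjusted p = 0.00345). The genes shared with hnRNPC (4) and hnRNPM (1) are too few for an exact test of direction to pass; with SRSF1 it gave an adjusted p of 1. COL12A1, FAM20B and TMEM245 fell after RBFOX2 depletion and rose by 0.25, 0.19 and 0.32 after SRSF1 depletion. Fold changes after RBFOX2 depletion correlated across genes at -0.0157 with hnRNPC, 0.0176 with hnRNPM and 0.181 with SRSF1, and by rank at 0.108, 0.159 and 0.135.

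These overlaps inherit the fragility of the RBFOX2 calls, and some calls of the other proteins were also lost by limma in other settings. E2F4 after hnRNPC depletion stood at 0.04 with the values as deposited (adjusted p = 0.881). After SRSF1 depletion C7orf50 stood at 0.21 as deposited (0.502) and at 0.07 against all 8 mock libraries (0.640). TRIM16L stood there at -0.33 (0.156) and -0.24 (0.0741). The count of 4 with hnRNPC was 15 and 8 without hnRNPC siRNA_2 replicates 1 and 3, 2 without hnRNPC siRNA_3 replicate 1, 1 without RBFOX2 siRNA_2 replicate 5 and 0 without any other RBFOX2 library or mock library of its set. The count with hnRNPM was 2 without mock oct replicate 1 and 0 without either mock library of the RBFOX2 set or the replicates 4 of both RBFOX2 siRNAs. The count with SRSF1 was 0 without those same 4 libraries and 2 without RBFOX2 siRNA_1 replicate 5. With the values as deposited, or with only the groups of each comparison in the fit, 0 genes overlapped in the same direction with any of the 3 proteins.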

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

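The tests of GC content after RBFOX2 depletion and of small RNA yield after hnRNPC depletion were chosen after the result was seen. The other tests in this part were set before their own result was seen. The GC correction and the library left out as standing apart, which 2 of them use, were chosen after the data were seen.

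Between the 2 hnRNPC siRNAs 1880 genes differed in the model of all groups, 541 with the values as deposited and 6 with only the groups of that comparison. Unequal depletion of HNRNPC was not seen in its own RNA, at -1.69 with siRNA_2 and -1.84 with siRNA_3 (limma adjusted p of the difference 0.492). Opposite signs with the 2 siRNAs, which it alone would not give, were found for 67.2% of those genes (1263 of 1880). The genes were picked for a difference, which favours opposite signs, so this share argues against unequal depletion as the whole cause without excluding it. The differences followed GC content only weakly (rank correlation 0.0595 across protein-coding genes), which argues against the GC trend as the main cause. After its correction 2572 genes differed. That correction also raised the number of genes called for each protein, so the higher count does not exclude a contribution. A single library has the values it needs: without siRNA_2 replicate 3 the count was 518, against 2210 without its partner replicate 1, so that library could carry much of the difference, although the count was also lower, 864 and 1171, without siRNA_3 replicates 3 and 1. Silencing of other transcripts by one siRNA sequence is open. The larger effect was downward for 58.9% of the genes (interval 56.7% to 61.2%), not clearly above the share set beforehand, with 357 of 529 for siRNA_3 and 751 of 1351 for siRNA_2. An even split is not the baseline, since among all hnRNPC calls 737 fell and 359 rose. The interval also takes genes as independent, so this share does not bear on the cause.

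Fold changes after RBFOX2 depletion followed GC content (rank correlation 0.425). A bias between libraries has the values it needs, because the mock libraries of that set differed from each other by 0.719 in the same correlation, and the trend may therefore come from library preparation. A trend of similar size was also seen for hnRNPM, with a correlation of 0.412 (0.235 for hnRNPC and 0.0937 for SRSF1). The hnRNPM trend rests on other libraries and mock sets, so it does not exclude a part peculiar to RBFOX2 depletion. Whether depletion shifted GC content in the RBFOX2 libraries stays open, their mean correlation lying 0.290 (SE 0.363) above that of their mock libraries. With the trend removed 47 genes were called for RBFOX2 instead of 19, with 10 of the 19 among them.

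Copies of U6, 7SK, 7SL and Y RNA genes rose after hnRNPC depletion, 37 of 499 tested against 5 that fell, with a median log2 fold change of 2.16 among those that rose but of 0.09, 0.31, 0.08 and 0.09 over all tested copies of each family. Without a test of enrichment, 3 of 36 U1, 2 of 19 U2 (1 fell) and 1 of 10 U4 copies, 4 of 17 EEF1A1P pseudogenes, 4 of 435 snoRNA genes (1 fell) and 8 of 201 ribosomal protein pseudogenes (5 fell) also rose. Reads moved from other copies of the same family were looked for as a net loss of TPM in the remaining genes. For U6 these held 2682 TPM more (SE 4037) beside a gain of 12356 in the risen copies, and for 7SL 12260 more (SE 5487, gain 4380), so no such loss was seen. For 7SK (1189 more, SE 9414, gain 838) and Y RNA (7675 more, SE 6570, gain 1804) a loss as large as the gain lies within 2 standard errors. A rise of the whole family could hide a loss, and TPM are not read counts, so moved reads stay open for all 4 families. A yield higher for all small RNAs alike would move them by a common amount. Their median shift was 0.16 (1361 genes, quartiles -0.11 and 0.43), and with it taken off 32 copies still rose and 6 fell. The risen copies were picked for their rise, which made this count likely in advance. It argues against such a yield as the whole cause without excluding it. An effect of hnRNPC on the copies themselves was not tested.

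Between the RBFOX2 siRNAs 257 genes differed, with siRNA_1 minus siRNA_2 at 0.63 for GCNT2, 0.46 for MAP3K1, 0.38 for LPHN2, -1.10 for THBD, -1.22 for IGFBP6 and -0.89 for LAMB3. Between the hnRNPC siRNAs, siRNA_2 minus siRNA_3 was 0.81 for FNIP2, 0.77 for TMEM87A, 1.22 for ATL3, -1.32 for PINK1, -0.78 for CPOX and -0.69 for SF3A3. Between the hnRNPM siRNAs 7 genes differed, with siRNA_1 minus siRNA_3 at 0.65 for AK4, -1.10 for YWHAH, -1.08 for PSAT1 and -0.75 for ANO6. Between the SRSF1 siRNAs 1 gene differed, AC006262.5 at 2.22.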

How the results depend on the processing

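The tests with the GC correction, with that correction and the replicate block, without the pair of libraries picked by eye, and of the gene lists without each library were chosen after the result was seen. All other choices were made before the data were examined. Values are given in the order RBFOX2, hnRNPC, hnRNPM, SRSF1 where all are present, and for results that changed the cause was not tested. The called genes numbered 19, 1096, 176 and 1593, the genes differing between siRNAs 257, 1880, 7 and 1, the overlaps with RBFOX2 in the same direction 4 (hnRNPC), 1 (hnRNPM) and 4 (SRSF1), and the list calls 17. Of 100 named calls, 52 were kept with the values as deposited, 80 against all 8 mock libraries and 49 with only a comparison's own groups, and 0 changed sign in any setting.

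With the values as deposited 4, 287, 42 and 249 genes were called, 22, 541 and 0 differed between the RBFOX2, hnRNPC and hnRNPM siRNAs, and the overlaps were 0, 0 and 0. A common total without small structured RNAs gave 6 genes for RBFOX2 and an overlap of 1 with hnRNPC, and no trend an overlap of 2 with hnRNPC. No filter gave 45 genes for RBFOX2 and 41 and 21 differences for hnRNPM and SRSF1. A filter at 5 TPM gave 46 genes for RBFOX2, overlaps of 14 with hnRNPC and 11 with SRSF1, and 11 list calls. A pseudocount of 0.1 gave 0 differences for SRSF1. Against all 8 mock libraries 3929 genes were called for RBFOX2 and 3527 for hnRNPC, with overlaps of 891, 52 and 252. The GC correction gave 47 genes and 479 differences for RBFOX2, 16 differences for hnRNPM, and overlaps of 11 with hnRNPC and 16 with SRSF1. Without the pair of libraries picked by eye 31 genes were called for RBFOX2 and 706 for hnRNPC, and 524 differed between the hnRNPC siRNAs. With only a comparison's own groups 1, 58 and 37 genes were called for RBFOX2, hnRNPC and hnRNPM, 0, 6 and 0 differed, and the overlaps were 0, 0 and 0. Single siRNAs gave 83 and 139 genes for RBFOX2, 2253 and 462 for hnRNPC, 115 and 48 for hnRNPM and 501 and 552 for SRSF1. An estimated correlation gave 0 list calls.

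With replicate number as a block 363, 2267, 355 and 2805 genes were called, 930, 3273, 23 and 6 differed, the overlaps were 77, 25 and 85, and 27 lists passed. With the GC correction as well the values were 477, 2699, 496 and 3549, 1441, 4028, 45 and 25, 118, 36 and 138, and 26. Deviations of libraries from their group mean were correlated across genes between groups. For libraries with the same number in a mock set these correlations were 0.0615 to 0.431 over 13 pairs of groups, 12 of them over 0.1. Across sets the correlations reached 0.278 in size, with either sign, over 53 pairs. The groups of a set also carry the same numbers, 1 and 3 in the oct set and 4 and 5 in the n4/n5 set. Both are hints of pairing, but what a shared number marks is not stated and a comparison has 2 pairs. Whether the fit with the block is the better one was not settled, and the main results rest on the fit without it.

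Leaving out each library leaves an arm with 1 sample, whose variance is then taken from the other groups. The called genes ranged over 1 to 17, 369 to 1200, 80 to 138 and 919 to 1238. The differences ranged over 29 to 228, 518 to 2210, 0 to 8 and 0 to 2, the overlaps over 0 to 15, 0 to 2 and 0 to 6, and the list calls over 13 to 26. The histone list was the one result that reversed. Its median was -0.10 after RBFOX2 depletion without mock_n4_n5 replicate 5 and 0.59 without replicate 4, against 0.22 with all libraries. After hnRNPC depletion it was -0.0937 without mock_oct replicate 1 and 0.55 without replicate 3, against 0.19.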

Other observations

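The tests of the 4 gene groups and of the 8 siRNAs together given here were chosen after the result was seen, the groups because some of their members had been seen to move, so they are hypotheses and not independent findings. In all, 16 tests of these groups were made and 16 classes of small RNA genes and gene families were also looked at. The tests of shuffled splits were set before.

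Targets of the oxidative stress factor NRF2 were lower after RBFOX2 depletion, with a median of -0.29 over 16 genes (camera adjusted p = 2.52e-13; adjusted p = 0.0351 with an estimated correlation), AKR1C2 and TRIM16L being the 2 that fell. GCLM stood at -0.40 (adjusted p = 0.0827) and ME1 at -0.44 (adjusted p = 0.0827). After SRSF1 depletion 4 fell, AKR1C1, AKR1C2, GCLC and TRIM16L, with a median of -0.23 (adjusted p = 1.62e-06; adjusted p = 0.158 with an estimated correlation). After hnRNPM depletion none passed, with a median of -0.12 (adjusted p = 0.00310; adjusted p = 0.345 with an estimated correlation). After hnRNPC depletion 1 fell, with a median of -0.07 (adjusted p = 0.288). TRIM16L (-0.64 to -0.01) and GCLC (-0.49 to -0.03) were below mock with all 8 siRNAs, in part by close to nothing. TRIM16L was called after RBFOX2 and SRSF1 depletion and GCLC only after SRSF1 depletion, so a change with every protein is not shown. A measurement of NRF2 protein and of its targets in new cultures, with a control siRNA, would test whether the pathway loses activity.

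After hnRNPC depletion the ID genes, which encode inhibitors of differentiation downstream of BMP signalling, rose, with ID2 at 1.00 (adjusted p = 0.000226), ID3 at 0.84, ID4 at 0.48 and an adjusted p of 8.42e-05 for ID1. BAMBI fell by 0.32 (8 genes, median 0.50, camera adjusted p = 9.29e-06; adjusted p = 0.0351 with an estimated correlation). Targets of MAP kinase signalling, feedback genes and others, also stood higher (16 genes, median 0.24, camera adjusted p = 3.83e-07, and 0.0351 with an estimated correlation). The 4 that rose were DUSP6 at 0.94 (limma adjusted p = 0.000744), SPRY2 at 0.68, ETV4 at 0.35 and ETV5 at 0.21. After SRSF1 depletion 4 of the 8 genes of the ID group rose and 1 fell (median 0.22, camera adjusted p = 0.0284, and 0.307 with an estimated correlation). ID2, ID3, ID4 and SMAD9 rose by 0.72, 0.48, 0.64 and 0.29, and BAMBI stood at -0.47. Antigen presentation genes gave HLA-DMB and PSMB9 as the 2 that rose after SRSF1 depletion (median 0.10, adjusted p = 0.0178; adjusted p = 0.346 with an estimated correlation). The same group had a median of -0.21 after hnRNPC depletion (1 fell, adjusted p = 0.0101; adjusted p = 0.345 with an estimated correlation) and 0.09 after hnRNPM depletion (adjusted p = 0.0135; adjusted p = 0.345 with an estimated correlation). The MAP kinase group had a median of 0.24 after RBFOX2 depletion (adjusted p = 5.92e-05; adjusted p = 0.0600 with an estimated correlation), with 0 genes called.

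Across all 8 siRNAs 932 genes kept one sign against their mock sets, where simulations without effects gave 469.6 on average and 528 at most. The simulations drew genes independently and held no trend shared by libraries, so their range is too narrow for a test. Of the 932 genes 357 also passed limma at an adjusted p under 0.05 in the mean of the 4 proteins, 158 rising and 199 falling. GUF1, a mitochondrial translation factor, was among those that fell, at -0.33 (adjusted p = 0.000394, and -0.56 to -0.11 with single siRNAs). After the correction for GC content, which all 8 contrasts followed (rank correlation 0.0582 to 0.378), 704 genes kept one sign against 472 simulated on average and 518 at most. No group received a control siRNA, so a response to siRNA as such cannot be separated here from a response to the proteins.

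Shuffled splits of the 8 libraries used a simpler fit on those libraries. For SRSF1 the real split called 1212 genes, 1 of 35 splits, and the highest other 12. The splits were taken over all 8 libraries and not within each mock set, so some of them follow the set in part. The count of splits therefore cannot exclude chance for this design. For hnRNPM the count of splits did not exclude chance: 44 genes were called with the real split and 1166 with the highest other, so 2 of 35 splits gave as many. That other split followed the mock set, which reflects the structure of the samples, and no remaining split called more than 4 genes.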
